A study of Pyrus pyrifolia with 6 samples.

How the data were processed

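Messenger RNA was sequenced from the pulp of Akibae pear (Pyrus pyrifolia) grown in an orchard, per the labels' protocols. Fruit had received a boron application or a control treatment, and each group had 3 libraries, numbered 1 to 3, per the labels. The dose, the stage at harvest, the form of boron and the nature of the control treatment are not given in the sources used here. Total RNA was extracted with a Trizol kit and libraries were made with an NEBNext Ultra RNA kit, per the labels' protocols. HISAT2 (no version given) is the only tool named in the submitters' processing notes. The read counter, its use of strand, the genome build and the authors' statistical test are not given in the sources used here, so genes are named and placed as the deposited table gives them, on its own scaffolds.

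The first deposited table lists 4291 genes with values for each library. These library values (signal, in the sense of normalized counts) are gene counts that the authors divided by 1 size factor per library. All 4291 values of each library were whole multiples of a single step, with deviations from a whole number of at most 1.31e-05, and the step gave back the reads. The recovered size factors were 1.03, 1.11 and 1.02 for boron libraries 1 to 3, and 1.00, 0.961 and 0.926 for control libraries 1 to 3. The authors' group means of the same signal equalled the means of the library values within 3.33e-05. Fold changes in the deposited table are log2 values of boron over control, per the file headers. The table also gives a p-value and an adjusted p-value for each gene, per the file headers. The largest adjusted p-value was 0.0499 and the smallest absolute log2 fold change was 1.00, so only genes that the authors had called are listed. Gene length in bases, a value of another kind, is as the authors gave it and was used for counts per kilobase. Descriptions, protein families and scaffold coordinates were taken from the same deposited table.

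The second deposited table holds 1 value for each of 42194 genes. It is a signal-to-noise score and not a fold change. The score that the authors deposited equals the difference of the group means over the sum of the group standard deviations. Each standard deviation is set to at least 0.2 of its mean, a mean of 0 counting there as 1 unit of the scale. This formula, applied to the library values of the first table, rebuilt the score of all 4291 shared genes within a tolerance of 1e-05, with a largest difference of 6.1e-07. The fit used a constant of 13.7 normalized counts per kilobase per unit of the scale, taken from the 221 genes with 1 group at 0. Values on that scale are called FPKM here.

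The design, the gene lists, the rule for named genes and most alternatives were fixed before the data were examined. The design had foreseen raw counts or FPKM for a wide set of genes. Because the deposited values were normalized counts, the test was limma 3.58.1 (trend and robust options, R 4.3.3) on log2(normalized count + 1), two-sided, over all 4291 listed genes, with Benjamini-Hochberg adjustment and a threshold of 0.05. Standard errors come from the same model. Because only genes called by the authors on these libraries are listed, counts of passing genes are not genome-wide, and a test of set enrichment against unchanged genes was not made. Each gene list was instead described by its numbers of higher and lower passing members, set against the other passing genes by Fisher's exact test (two-sided, SciPy 1.17.1), with adjustment over the 20 lists that had at least 5 members. Members of a list need not be independent of each other, and the Fisher test treats them as if they were.

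There were 24 lists, each a set of patterns on the gene description. They covered boron and water channels, pectin and hemicellulose modification, cell wall synthesis, sugar and sorbitol metabolism, sugar transport, organic acid metabolism, ethylene, auxin, and gibberellin, abscisic acid and other hormones. They also covered lignin and phenylpropanoid enzymes, flavonoid enzymes, oxidative stress enzymes, heat shock proteins and chaperones, calcium signalling, defence, WRKY, NAC and MYB transcription factors, photosynthesis, cytosolic ribosomal proteins, and histones and cell cycle. Markers of peel, vascular tissue, seed, suberin and microbial or viral sequence made up the rest.

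The rule for named genes took the 6 largest rises and 6 largest falls among genes that passed, had all 3 values of a group on one side of the other group, reached a mean of 5 FPKM in the higher group and had an informative description. From each list of first interest it also took the 2 members with the largest absolute change among those that met the same conditions, the mean of 5 FPKM included, and it took the called member with the highest mean from each of the other lists. The rule named 39 genes, and a further 56 were chosen after their values were seen and are identified as such. A gene at 0 reads in all libraries of a group has a fold change given as a lower bound, against a floor of 3 reads over the group. A gene with 1 to 3 reads in a group has its ratio with an exact 95% interval. Such bounds and intervals cover counting error only.

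Single quantities of the libraries were compared by exact permutation tests (two-sided), for which the smallest p with 3 against 3 libraries is 0.1. The depth of whole libraries is not given in the sources used here. The reads recovered in the listed genes came to 1941693, 2056668 and 1926422 in the boron libraries and 2042566, 1943960 and 1914312 in the control libraries. Between libraries of 1 group the squared differences in reads were on average 3.74 to 8.50 times what counting alone gives. These are means of chi-square per degree of freedom over genes with at least 20 reads. They do not hold gene by gene, and single genes can spread less.

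Alternatives were a block for the replicate number, quantile normalization, limma without trend, several filters on low values, a pseudocount of 0.1, log2(FPKM + 1), a fold-change threshold and leaving out each library in turn. On the recovered reads, edgeR 4.0.16 (quasi-likelihood test) was run with TMM and with DESeq2-type size factors computed over the listed genes, and DESeq2 1.42.0 with the authors' size factors. The count test with the authors' size factors, edgeR on the recovered reads, called 4257 genes (3124 higher, 1133 lower). The main limma test called as many, but the sets differ, with 4247 genes shared. Alternatives chosen after seeing the data were that edgeR fit, its version with a replicate block, and 3 for the gene lists (genes with a mean of at least 100 normalized counts, 1 entry per description, and directions exchanged within classes of abundance). DESeq2-type and TMM scaling over the listed genes take most of the listed genes to be unchanged, and quantile normalization takes all libraries to have the same distribution of values, whereas the listed genes were selected for having changed.

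The tests were tried on simulated data of 4291 genes with 200 changed for the boron and control comparison. At 2-fold, limma recovered 62%, edgeR 62% and DESeq2 61% of 100 changed genes. At 4-fold they recovered 97%, 94% and 92%. False calls among 4091 unchanged genes numbered 10, 9 and 11. The changes were put only into genes with a mean of at least 10 normalized counts. In the real data nearly all listed genes passed, so these rates are not those of the main test. For the list test, 4.1% of 2000 random lists of 50 genes had an unadjusted p under 0.05. Of planted lists of that size with a higher share of 95%, 98.8% did. Members were drawn independently, so 98.8% is not the power for smaller lists, weaker shifts or adjusted p-values. Tables were handled in Python 3.11.15 with pandas 2.3.3 and NumPy 2.4.6.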

Results

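Pulp of Akibae pear was compared between fruit given a boron application and control fruit, to ask which transcripts differ with boron, a plant nutrient that cross-links pectin in the cell wall. There were 6 mRNA libraries, 3 per group. Values for each library were at hand for 4291 genes, which the authors had chosen as different between the groups on these same libraries. The libraries held between 1914312 and 2056668 reads in those genes. Means are in normalized counts with the SD over n = 3 libraries, boron first unless stated, and log2 fold changes (boron over control) are from limma with their SE. The labels do not say that the libraries of a group came from separate fruits or trees, so p-values measure only the spread between these libraries.

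Boron-treated pulp had little mRNA of a pair of genes for ACC oxidase, the enzyme that makes ethylene from its precursor. LOC103943975 (ACC oxidase 1) had 2.28 ± 2.47 normalized counts in boron libraries against 2095 ± 98.7 in control libraries (n = 3 each), a log2 fold change of -9.66 ± 0.51 (limma, adjusted p = 6.61e-08). A tonoplast water channel, aquaporin TIP1-3-like (LOC103929061), went the other way, from 0 reads in every control library to 209 ± 21.0 normalized counts, which is at least 201-fold higher. A gene for a probable boron transporter (LOC103956856, chosen after its values were seen) fell from 3601 ± 111 to 234 ± 28.2. Among the gene lists, genes of photosynthesis, defence, heat shock proteins, and histones and the cell cycle were higher in boron fruit more often than the other listed genes, and genes of sugar and sorbitol metabolism less often. Of these calls, that of photosynthesis held in all 23 alternatives, and those of heat shock proteins, defence, histones, and sugar metabolism were lost in 1, 3, 4 and 4 of them.

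Of the 4291 listed genes, 4257 passed the limma test, 3131 higher and 1126 lower in boron fruit (73.5% higher), and 34 did not. The groups did not overlap in 4192 genes (97.7%), where chance gives 10%. Since the genes had been selected on these libraries, the count describes the listed genes and is no genome-wide figure. The split depended on the scaling. TMM and DESeq2-type scaling over the listed genes take most of these selected genes to be unchanged, which draws the split towards even. With TMM over the listed genes, 1318 genes were higher and 1242 lower (51.5% higher). With DESeq2-type size factors over the listed genes the numbers were 1386 and 1216 (53.3%), and with quantile normalization 1522 and 1145 (57.1%). These scalings shifted the median log2 fold change of the listed genes, 1.62 with the authors' size factors, by -1.42, -1.37 and -1.25, and 2444, 2512 and 2648 of the passing genes passed again in the same direction. Among 1607 genes with a mean of at least 5 FPKM, 1604 passed and 60.4% of these were higher.

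The share of higher genes, taken over all listed genes by the direction of the authors' fold change, fell with abundance. It was 85.2% (exact 95% interval 81.9 to 88.0) among genes with a mean of up to 10 normalized counts and 42.8% (37.4 to 48.3) among genes with a mean over 1000. The 10 most abundant genes of a library took 19.7% ± 0.380 of the listed reads in boron libraries and 29.1% ± 0.403 in control libraries (n = 3, exact permutation p = 0.1). Listed genes at 0 reads numbered 71.0 ± 3.61 in boron and 413.0 ± 37.3 in control libraries (exact permutation p = 0.1). Listed reads per library averaged 1974928 ± 71199.8 in boron and 1966946 ± 67146 in control libraries (exact permutation p = 0.8). The authors' size factors averaged 1.05 ± 0.0488 and 0.963 ± 0.0386 (exact permutation p = 0.1). A p of 0.1 is the smallest that 3 against 3 libraries can give. Correlations of log2 values across listed genes were 0.965 to 0.972 within groups and 0.697 to 0.711 between them. Genes are not independent replicates, and these genes had been selected for differing.

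**Figure D1:**
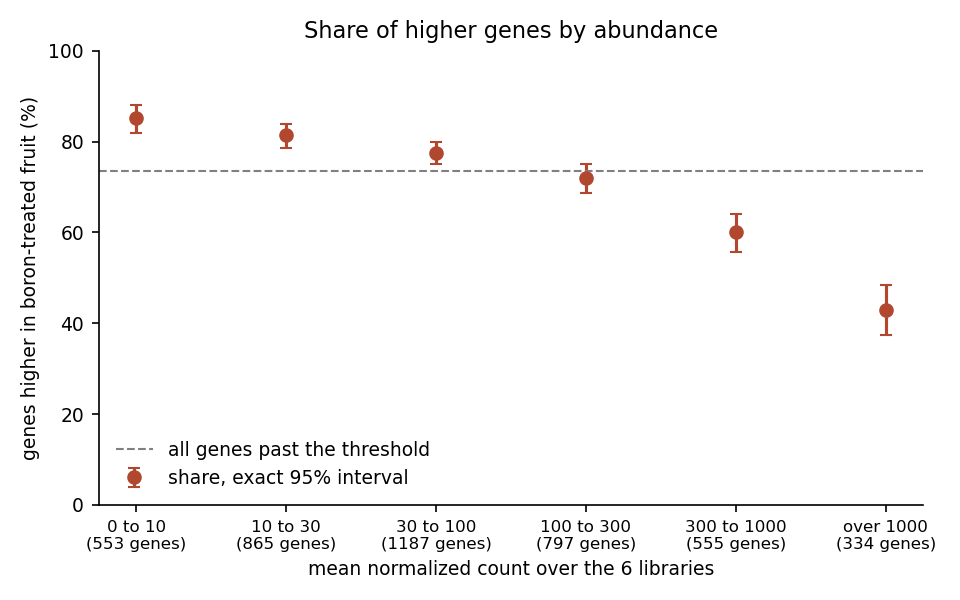
Share of listed genes that were higher in boron fruit by the authors' fold change (vertical axis, %), with exact 95% intervals. The horizontal axis is the mean normalized count over the 6 libraries. The dashed line is the share higher among all genes that passed limma, 73.5%. The share goes from 85.2% among the least abundant genes to 42.8% among those with a mean over 1000.

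The largest rises and falls, by the rule for named genes, were large against the spread of the libraries. LOC103962567, a BURP domain protein similar to the drought-responsive RD22 (scaffold NW_008988270.1, 122072 to 126078), rose from 15.5 ± 4.50 to 5060.3 ± 324 normalized counts, a log2 fold change of 8.30 ± 0.19 (limma, adjusted p = 9.12e-11). LOC103950120, similar to methionine gamma-lyase, an enzyme that breaks down methionine, had 305 ± 25.5 against 1.39 ± 0.604. A CCCH zinc finger gene (LOC103929638) had 193 ± 2.22 normalized counts in boron libraries and 2 reads in all control libraries together, a ratio of 278 with a 95% counting interval of 76.8 to 2304. Among the falls were an oligopeptide transporter 1-like gene (LOC103940709), with 4.15 ± 1.25 against 3278 ± 149, and a 2-hydroxyisoflavanone dehydratase-like gene (LOC103930798), with 6.94 ± 4.84 against 2865 ± 111. The probable RNA-binding protein ARP1 (LOC103966658) had 2 reads in the boron libraries and 146 ± 21.7 normalized counts in control, a ratio of 230.2 (63.3 to 1907). Counting intervals and bounds cover counting error only.

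All 95 genes named in the text passed the limma test with the groups apart, at an adjusted p of at most 0.00203. Genes outside the rule were chosen after their values were seen, and each is given below as a further gene. In each of the 24 lists, as many members passed when adjusted over the list alone as when adjusted over all 4291 genes. The lists were fixed beforehand, but their members were chosen by the authors on these libraries, so the number that passed is not independent evidence. Several members carry the same description, and reads of near-identical copies may have been split or shared between them, which leaves the values of single copies uncertain. The same holds for overlapping and antisense genes, since the use of strand in counting is not given.

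Boron and water channels had 20 listed members, of which 18 rose and 2 fell (Fisher's exact test against the other passing genes, adjusted p = 0.361). With TMM and DESeq2-type scaling over the listed genes, 12 of 14 and 13 of 15 passing members were higher (adjusted p = 0.0419 and 0.0343, in a range of 0.0343 to 0.840 over 23 alternatives). Aquaporin TIP1-3 (LOC103930013), the other member that the rule named, had 105 ± 32.1 normalized counts against 2 reads in control, a ratio of 151 (41.4 to 1251). Further members were aquaporin TIP1-1-like (LOC103941273), with 23395 ± 2491 against 3325 ± 117, and the plasma membrane aquaporin PIP1-4 (LOC103936441), with 18141 ± 1484 against 5913 ± 604, a call that TMM scaling ended. The boron transporters, both further genes, whose kind moves borate across membranes, went in opposite directions. Probable boron transporter 2 (LOC103956856, scaffold NW_008988184.1, 139300 to 145094) had a log2 fold change of -3.95 ± 0.10 (limma, adjusted p = 1.48e-10). Probable boron transporter 6 (LOC103927569) rose from 13.2 ± 5.67 to 41.0 ± 8.42 (limma, adjusted p = 0.00203), a call lost with quantile, TMM and DESeq2-type scaling.

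Pectin and hemicellulose modification had 65 listed members, of which 48 rose, 16 fell and 1 did not pass (Fisher's exact test, adjusted p = 1), against 33 higher and 18 lower with TMM over the listed genes. Both members that the rule named encode xyloglucan endotransglucosylase/hydrolases, which join and trim xyloglucan chains of the wall: protein B (LOC103944733) had 1170.3 ± 90.3 against 11.2 ± 3.63, and protein 32 (LOC103965682) had 276 ± 33.6 against 5.07 ± 5.11. Further members were expansin-A1 (EXP5), a wall-loosening protein, with 12352 ± 221 against 2296 ± 144, and a beta-galactosidase (LOC103943992), with 74.4 ± 13.1 against 2977 ± 165. Also among the further members, a pectinesterase (PME4) fell from 13731 ± 1011 to 4633 ± 270, and a polygalacturonase inhibitor (LOC103947767) from 10837 ± 788 to 2431 ± 134. Of 29 genes of cell wall synthesis, 21 rose and 8 fell (adjusted p = 1; 11 and 8 with TMM). The most abundant of them, a cellulose synthase A subunit 2-like gene (LOC103942164), fell from 13290 ± 525 to 2417 ± 32.6, and a further member, a leucine-rich repeat extensin-like gene (LOC103962730), rose from 59.7 ± 7.17 to 1248 ± 77.6.

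In sugar and sorbitol metabolism 12 genes rose and 15 fell (4 and 15 with TMM), a lower share of rises (44.4%) than among the other passing genes (Fisher's exact test, adjusted p = 0.00589, 0.00214 to 0.111 over 23 alternatives). The call was lost in 4 alternatives: a mean of at least 1 FPKM (0.0878), of at least 5 FPKM (0.111), of at least 100 normalized counts (0.109), and 1 entry per description (0.0583). The median log2 fold change of the list, -1.30, was -2.92 relative to that of all listed genes. Only genes with an absolute log2 fold change of at least 1.00 are listed, so part of this distance is the gap between rises and falls. A sorbitol dehydrogenase-like gene (LOC103933316), for the enzyme that turns sorbitol into fructose, rose from 23.1 ± 3.36 to 235 ± 6.92. Sucrose-phosphate synthase 1, an enzyme of sucrose synthesis, fell from 426 ± 21.6 to 87.3 ± 11.4 (LOC103946723) and, in a further gene, from 187 ± 10.3 to 31.9 ± 10.7 (LOC103937917). Another further gene, similar to sucrose synthase (LOC103935319), fell from 459 ± 9.25 to 121 ± 17.1. A more abundant sorbitol dehydrogenase-like gene (LOC103960512, a further gene) rose from 1770 ± 18.7 to 4474 ± 34.0, but with TMM and DESeq2-type scaling it did not pass (log2 fold changes -0.10 and -0.057).

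Sugar transport had 25 listed members, of which 20 rose, 4 fell and 1 did not pass (Fisher's exact test, adjusted p = 0.793), against 13 higher and 4 lower with TMM. The bidirectional sugar transporter N3-like gene (LOC103941020), of the SWEET type that lets sugars cross membranes along their gradient, fell from 6843 ± 328 to 165 ± 10.4, a log2 fold change of -5.36 ± 0.08 (limma, adjusted p = 7.02e-12). Putative polyol transporter 1 (LOC103929477) had 171 ± 14.0 normalized counts in boron libraries and 1 read in control, a ratio of 496 (88.6 to 19612). A further gene, similar to a sucrose transport protein (LOC103964096), rose from 31.1 ± 13.2 to 256 ± 39.3. Organic acid metabolism split into 5 rises and 6 falls (adjusted p = 0.261), or 2 and 6 with TMM. Tonoplast dicarboxylate transporter-like genes, whose products carry malate into the vacuole, moved apart: LOC103942769 fell from 2798 ± 273 to 1168 ± 52.2 and the further gene LOC103943766 rose from 373 ± 38.4 to 2554 ± 265. Further members were a phosphoenolpyruvate carboxylase-like gene (LOC103947929), which rose from 544 ± 23.4 to 2051 ± 48.9, and mitochondrial citrate synthase (LOC103954922), which fell from 1351 ± 13.5 to 575 ± 25.0.

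Of 60 ethylene genes, 43 rose and 17 fell (Fisher's exact test, adjusted p = 1), against 20 higher and 18 lower with TMM and 21 and 18 with DESeq2-type scaling. ACC oxidase genes did not move together. Besides LOC103943975 (scaffold NW_008988062.1, 1124704 to 1126213), the ACC oxidase 1 gene LOC103948231 fell from 1064 ± 115 to 8.34 ± 3.65, while the further gene LOC103954990 (ACC oxidase) rose from 133 ± 16.9 to 1149 ± 34.7. Among ethylene-responsive transcription factors, further genes were RAP2-4-like (LOC103962212), which rose from 1239 ± 84.1 to 4415 ± 425, and ERF098-like (LOC103939663), which fell from 1415 ± 180 to 28.5 ± 1.5. Of 53 auxin genes, 38 rose and 15 fell (adjusted p = 1), whereas falls were in the majority with TMM (12 higher, 18 lower) and DESeq2-type scaling (12 and 17). The small auxin-responsive gene SAUR72 (LOC103950232) rose from 28.6 ± 8.40 to 1285 ± 43.6, the auxin-induced 22D-like gene (LOC103945994) fell from 152 ± 17.7 to 1.55 ± 0.998, and the further gene PIN-LIKES 5-like (LOC103959162), of a family of auxin carriers, rose from 126 ± 7.20 to 2028 ± 73.5.

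Among 45 genes of gibberellin, abscisic acid and other hormones, 33 rose and 12 fell (Fisher's exact test, adjusted p = 1), against 17 higher and 14 lower with TMM. A gibberellin 3-beta-dioxygenase 1-like gene (LOC103935387), for the step that makes active gibberellins, fell from 1216 ± 82.6 to 37.6 ± 4.30, and a TIFY 3B-like gene (LOC103959124), of the family of jasmonate repressors, rose from 52.9 ± 11 to 1209 ± 34.6. Further members were a cytokinin dehydrogenase 7-like gene (LOC103927480), which fell from 28756 ± 2786 to 6867 ± 268, and the abscisic acid receptor PYL9 (LOC103929341), which rose from 277 ± 26.0 to 947 ± 110.2. Lignin and phenylpropanoid genes numbered 19 rises and 7 falls (adjusted p = 1), or 10 and 7 with TMM. Both genes named there, each similar to cinnamoyl-CoA reductase 1, fell: LOC103963803 from 143 ± 24.6 to 1.96 ± 3.40, and LOC108867111 from 176 ± 38.5 normalized counts to 2 reads in the boron libraries, a ratio of 280.0 (77.1 to 2318). Of 15 flavonoid genes, 12 rose and 3 fell (adjusted p = 1), or 7 and 3 with TMM. The most abundant of them, the 2-hydroxyisoflavanone dehydratase-like gene LOC103930798 given above, fell from 2865 ± 111 to 6.94 ± 4.84. The further gene LOC103957850, similar to anthocyanidin reductase, rose from 120 ± 6.73 to 482 ± 43.2.

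Photosynthesis genes rose together: 64 of 66 were higher in boron fruit (97.0%; 58 higher and 2 lower with TMM), with a median log2 fold change of 3.81, 2.19 above that of all listed genes (Fisher's exact test, adjusted p = 1.38e-05, 1.5e-13 to 0.0141 over 23 alternatives). Further genes were oxygen-evolving enhancer protein 1 (LOC103967609), a subunit of photosystem II, which rose from 75.8 ± 14.9 to 841 ± 123, and the chlorophyll a-b binding protein CP26-like gene (LOC103956592), which rose from 105 ± 19.6 to 782 ± 64.8. The most abundant member went against the list. It is a gene similar to the small chain of ribulose bisphosphate carboxylase, the carbon-fixing enzyme (LOC103928816), and it fell from 12152 ± 618 to 5758 ± 538, while a further small-chain gene (LOC103934623) rose from 604 ± 29.8 to 2304 ± 157. The other member that fell was a psbY-like gene of photosystem II (LOC103926797, a further gene), from 493 ± 50.9 to 192 ± 4.55. Beside these genes, 16 of 18 peel markers (epidermis, cuticle and wax) were also higher (adjusted p = 0.459, 0.0419 to 0.769 over 23 alternatives), with an adjusted p of 0.0419 under TMM and 0.0484 under DESeq2-type scaling.

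Among heat shock proteins and chaperones, 31 genes rose and 1 fell, or 15 and 2 with TMM (Fisher's exact test, adjusted p = 0.00489, 0.000371 to 0.0583 over 23 alternatives), and the call was lost with 1 entry per description (0.0583). The median log2 fold change was 2.07, 0.45 above that of all listed genes. The median of all listed genes includes the falls. A list of nearly all rises can therefore lie above it without rising more than other rising genes. The same limit applies to the distances given for photosynthesis and for histones and cell cycle. Further genes were a heat shock 70 kDa protein (LOC103956001), which rose from 418 ± 39.8 to 5188 ± 495, and a gene similar to small class I heat shock proteins (LOC103936226), which rose from 385 ± 20.5 to 3707 ± 251. The most abundant member, heat shock cognate 70 kDa protein 2 (LOC103948411), had 17821 ± 1436 against 8053 ± 204, and passed as lower in boron fruit with TMM and DESeq2-type scaling (log2 fold changes -0.29 and -0.25). The member that fell was a DnaJ chaperone (LOC103953319, a further gene), from 79.6 ± 14.4 to 30.9 ± 6.75. The list also took in a nematode resistance-like gene by its name HSPRO2 (LOC103942396, a further gene), which is no heat shock protein and rose from 259 ± 7.59 to 1485 ± 58.7.

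Defence genes numbered 90 rises and 11 falls, or 34 and 20 with TMM (Fisher's exact test, adjusted p = 0.000944, 0.000371 to 0.209 over 23 alternatives). The call was lost with a mean of at least 5 FPKM (0.173), TMM (0.209) and DESeq2-type scaling (0.0575), and the list's median log2 fold change, 1.53, was -0.09 relative to that of all listed genes. The most abundant member, MLP-like protein 328 (LOC103943021), of the family of major latex proteins, had 55231 ± 8020.4 normalized counts against 13519 ± 331. Further members were the pear allergen Pyr c 1 (LOC103959359), a pathogenesis-related protein of the Bet v 1 family, with 3600.2 ± 57.7 against 749 ± 96.8, and thaumatin-like protein 1 (LOC103967808), with 1644 ± 117 against 503 ± 44.8.

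Histones and cell cycle genes had 55 listed members, of which 51 rose, 3 fell and 1 did not pass, against 19 higher and 4 lower with TMM (Fisher's exact test, adjusted p = 0.000944, 0.000854 to 0.663 over 23 alternatives). Their median log2 fold change was 2.49, 0.87 above that of all listed genes. The call was lost with quantile normalization (0.174) and with a mean of at least 1 FPKM (0.0878), 5 FPKM (0.373) or 100 normalized counts (0.663). Further genes were a histone H4-like gene (LOC103963569), which rose from 97.8 ± 58.9 to 280.1 ± 43.8 (a call that quantile, TMM and DESeq2-type scaling ended), and a cyclin-D3-1-like gene (LOC103950566), which rose from 61.8 ± 7.84 to 215 ± 43.4 (ended by TMM and DESeq2-type scaling). The cyclin-dependent kinase inhibitor 6-like gene (LOC103964480), the most abundant member that passed, had 980.1 ± 29.7 against 478 ± 50 and passed as lower in boron fruit with TMM and DESeq2-type scaling (log2 fold changes -0.40 and -0.36). The members that fell, all further genes, were a cyclin-D5-1-like gene (LOC103951043) and kinesin-4-like genes (LOC103938335 and LOC103954823), with log2 fold changes of -1.52, -1.0 and -1.61.

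Oxidative stress enzymes had 31 listed members, of which 20 rose, 10 fell and 1 did not pass (Fisher's exact test, adjusted p = 0.815), whereas falls were in the majority with quantile normalization (9 higher, 11 lower) and with TMM and DESeq2-type scaling (7 and 11 in each). Peroxidase 42-like (LOC103951047) rose from 17.6 ± 2.41 to 1637 ± 124, peroxidase A2-like (LOC103964015) from 42.7 ± 11.4 to 368 ± 58.4, and a further peroxidase 42-like gene (LOC103948174) from 18021 ± 546 to 54773 ± 371. Calcium signalling genes numbered 31 rises and 11 falls (adjusted p = 1), or 14 and 12 with TMM and with DESeq2-type scaling. A calmodulin-binding protein 25-like gene (LOC103962332) rose from 1144 ± 32.0 to 5811 ± 391, and a further gene similar to chloroplast calcium-transporting ATPase 1 (LOC103951070) fell from 4372 ± 94.7 to 1484 ± 72.0. Of 50 WRKY, NAC and MYB transcription factors, 37 rose and 13 fell (adjusted p = 1), whereas falls were in the majority with TMM (8 higher, 13 lower) and DESeq2-type scaling (9 and 13). NAC transcription factor 56 (LOC103927424) fell from 12944 ± 358 to 5208 ± 131, and a further gene, NAC domain-containing protein 72 (LOC103966975), rose from 160.2 ± 6.29 to 595 ± 38.9.

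**Figure D2:**
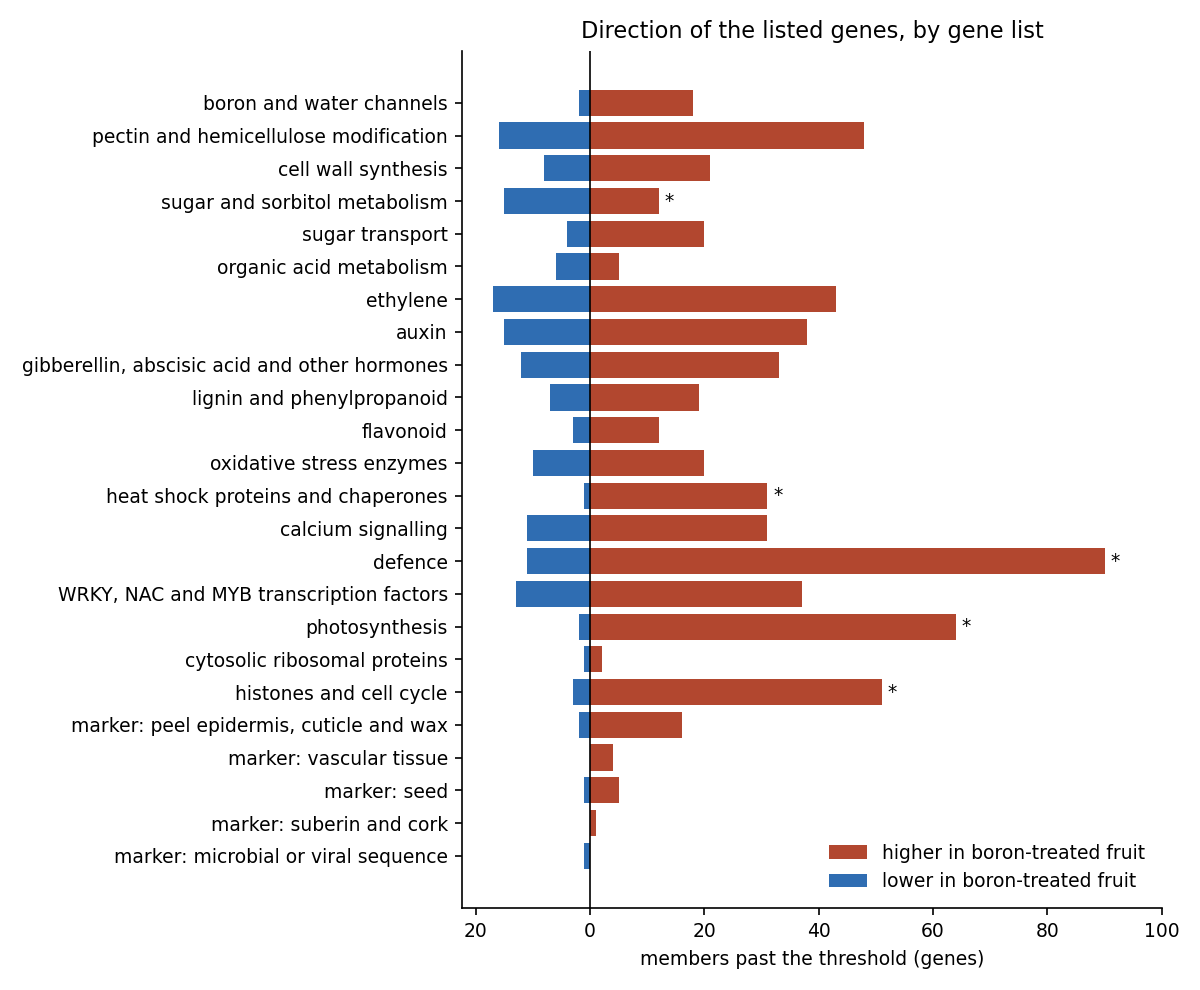
Numbers of passing members (horizontal axis, genes) that were higher in boron fruit (red bars, to the right) or lower (blue bars, to the left) for each of the 24 gene lists; asterisks mark the 5 lists whose direction differed from the other passing genes by Fisher's exact test. Photosynthesis has 64 higher and 2 lower members, and sugar and sorbitol metabolism 12 and 15, while auxin, oxidative stress and WRKY, NAC and MYB genes had more lower than higher members with TMM scaling, as did cytosolic ribosomal proteins (0 and 1).

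Lists of other tissues and sources were small. Peel markers included a GDSL esterase/lipase 1-like gene (LOC103930686), the most abundant, which fell from 931 ± 133 to 305 ± 32.2, and a further gene, non-specific lipid-transfer protein 2 (LOC103950629), which rose from 84.6 ± 7.95 to 643 ± 17.6. Of 6 seed markers, 5 rose and 1 fell (Fisher's exact test, adjusted p = 1), or 3 and 1 with TMM. The one that fell was a legumin B-like gene (LOC103946296), from 2235 ± 167 to 931 ± 104. Lists with fewer than 5 members were not tested. All 4 vascular markers rose (2 passed with TMM, both higher), with 241 ± 11.4 normalized counts for SIEVE ELEMENT OCCLUSION B-like (LOC103938158) against 3 reads in control, a ratio of 233 (79.3 to 1130.3). The most abundant of them, callose synthase 7-like (LOC103965925), had 413 ± 32.5 against 168 ± 33.9, but with TMM and DESeq2-type scaling it did not pass (log2 fold changes -0.14 and -0.10). The 1 suberin marker, a cytochrome P450 86B1-like gene (LOC103945558), rose from 296 ± 8.84 to 976 ± 76.4. The 1 gene caught by the microbial pattern, similar to a proline synthase co-transcribed bacterial homolog (LOC103951394), is listed on a pear scaffold and fell from 747 ± 162 to 351 ± 47.1. Of 3 cytosolic ribosomal protein genes 2 rose and 1 fell, whereas with TMM, DESeq2-type and quantile scaling only the fall passed. The gene that fell was 60S ribosomal protein L32-1-like (LOC103943557), from 1146 ± 137 to 568 ± 32.6.

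**Figure D3:**
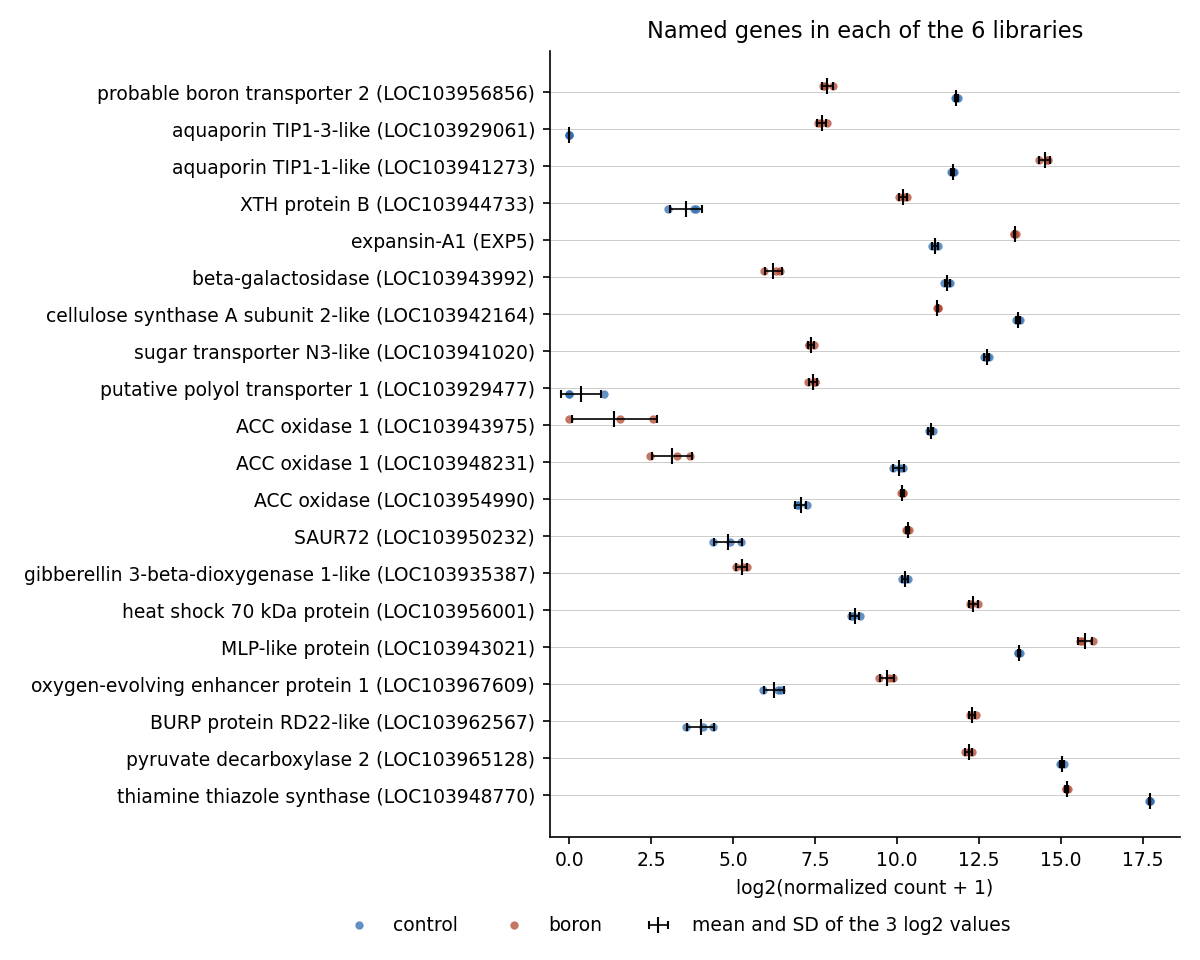
Values of 20 named genes in each library as log2(normalized count + 1) (horizontal axis), with boron libraries in red, control libraries in blue, and the mean and SD of the 3 log2 values in black. The groups are apart in each gene shown, with ACC oxidase 1 (LOC103943975) at 2.28 normalized counts in boron and 2095 in control, and aquaporin TIP1-3-like (LOC103929061) at 209 and 0.

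Against the authors' deposited table, all 4257 passing genes had the same direction, and the limma fold changes ranked the genes much as the deposited ones did (Spearman's rho = 0.986 across 4291 genes, given without a p since genes are not replicates). The authors' deposited table has 3146 genes higher and 1145 lower in boron fruit (73.3% higher). Both used the same libraries and size factors, so the match is not independent evidence. With edgeR on the recovered reads, TMM over the listed genes left 2461 genes that passed in the authors' direction, DESeq2-type scaling left 2527, and limma with quantile normalization left 2667.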

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

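Alternatives chosen after seeing the data were edgeR on the recovered reads with the authors' size factors, its version with a replicate block, and for the gene lists a mean of at least 100 normalized counts, 1 entry per description and directions exchanged within abundance classes. Of 20 alternatives for the number of passing genes, 16 gave between 3151 and 4291, within 1.5 times the 4257 reported. Those that moved it were quantile normalization (2667 genes, 57.1% higher, 2667 in the authors' direction), TMM (2560 genes, 51.5% higher, 2461 in the authors' direction), DESeq2-type size factors (2602 genes, 53.3% higher, 2527 in the authors' direction) and a mean of at least 5 FPKM (1604 genes, 60.4% higher, 1604 in the authors' direction). The last tested fewer genes. The others brought the median log2 fold change of the listed genes from 1.62 to 0.37 (quantile), 0.20 (TMM) and 0.24 (DESeq2-type). Leaving out 1 library gave 4206 to 4228 genes, 73.5% to 73.6% higher, 4206 to 4228 in the authors' direction, and 5 lists past the threshold each time. Lists past the threshold numbered 5 as reported and 2 to 6 over 23 alternatives: 3 with a mean of at least 1 FPKM, 2 with 5 FPKM, 3 with 100 normalized counts and 3 with 1 entry per description. Fewer genes were counted in each of these, and the cause was not tested further.

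Over 455 values for lists, 439 kept their direction and side of the threshold, 12 fell short of it, 4 newly passed it and 0 reversed. Over 1884 values for named genes, 1867 kept both, 9 fell short and 8 changed sign. As log2 fold changes with TMM and DESeq2-type scaling, those that passed with the opposite sign were heat shock cognate 70 kDa protein 2 (LOC103948411, -0.29 and -0.25) and cyclin-dependent kinase inhibitor 6-like (LOC103964480, -0.40 and -0.36). The other 4 values lay near 0 and did not pass: callose synthase 7-like (LOC103965925, -0.14 and -0.10) and sorbitol dehydrogenase-like (LOC103960512, -0.10 and -0.057). The replicate block gave 4258 genes with limma and 4266 with edgeR and changed no call of a list or named gene. Same-numbered libraries did not deviate together (r from -0.0389 to 0.0256 over 3 pairs, with 1 boron library closest to its own number). The planned tests of whole sets with preset or estimated correlation, blocked or self-contained, were not run because only called genes are listed. Genes with few reads limit the folds: 193 genes had 0 reads in every control library and 28 in every boron library.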

Other observations

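The tests of protein families, of the glycolysis, fermentation and ripening lists, of library scaling, of the detection floor and of peel tissue were chosen only after the result was seen, except that the direction for glycolysis and fermentation genes not yet looked at, and the other splits of the libraries, were set down beforehand.

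Some of the most abundant transcripts among the listed genes belong to none of the fixed lists. All genes first named in this part were chosen after their values were seen. Thiamine thiazole synthase (LOC103948770), an enzyme of vitamin B1 synthesis and the most abundant listed gene, fell from 215570.2 ± 2662 normalized counts in control to 37275 ± 1015 in boron libraries (SD, n = 3 each). Genes for metallothioneins, small proteins that bind metals, were among the falls: metallothionein-like protein 1 (LOC103944923) from 66483 ± 3246 to 8146 ± 555, and type 2 (LOC103944925) from 77346 ± 4792 to 31410 ± 1253. Metallothionein genes were not counted as a group. A gene similar to TATA-binding protein-associated factor 2N (LOC103931680) rose from 5344 ± 393 to 72829 ± 2695. Among unlisted genes, which have only the authors' deposited score, 13366 were above 0 and 12927 below 0, and 219 had a score beyond 1.67 in size, the score of a 2-fold difference at the smallest spread that the score allows (168 above and 51 below).

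Of 60 protein families with at least 8 passing members, 3 differed in direction from the other passing genes by Fisher's exact test. Universal stress proteins had 1 rise and 9 falls (adjusted p = 0.00283). The most abundant of those named here, Slr1101-like (LOC103962306), fell from 8168 ± 340.2 to 3839 ± 221, and the 1 that rose, PHOS32-like (LOC103938025), went from 0 reads in control to 82.4 ± 17.7 normalized counts, at least 79.6-fold higher. The protein kinase family Pkinase had 129 rises and 22 falls (adjusted p = 0.0110). Another kinase family, Pkinase_Tyr, had 88 rises and 17 falls and did not pass (Fisher's exact test, adjusted p = 0.118). Glycosyltransferases of the family that holds sucrose and starch synthases had 4 rises and 10 falls (adjusted p = 0.0110), and share members with the sugar list. Subtilases, proteases of the apoplast, had 18 rises and 0 falls (adjusted p = 0.0711, and 0.00809 when directions were exchanged within abundance classes), with SBT1.5 (LOC103948579) at 12846 ± 869 against 2904 ± 110.4 and SBT1.3 (LOC103940273) at 3713 ± 76.4 against 255 ± 62.6. With TMM over the listed genes, universal stress proteins had 1 higher and 9 lower members, and the Pkinase family 64 and 26. Glycosyltransferases had 0 and 10 with that scaling, and subtilases 14 and 1.

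The 4257 genes that passed were set against other splits of the 6 libraries. The 10 splits into 3 and 3 included 1 with as many genes, the real one. The highest other split had 0 genes by limma, with 14 to 25 genes at an unadjusted p under 0.05. These splits are too few for a share under 0.05, and the genes had been selected for differing in the real split, which favours it.

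More listed genes were higher than lower (73.5%), and a candidate explanation is a scaling factor that lifted all boron values. Such a factor would lift the unlisted genes too, and 50.8% (exact 95% interval 50.2 to 51.4) of their nonzero scores were above 0. This cannot decide the question, since a shift shared by most genes would be hidden by size factors set to balance them. The unlisted genes are also those left after the called genes were taken out. TMM, DESeq2-type and quantile scaling over the listed genes alone brought the share to 51.5%, 53.3% and 57.1%. These scalings take most listed genes to be unchanged, or all libraries to have the same distribution, so they draw the share towards even and cannot decide it either. Genes near the detection floor are another candidate. With the authors' size factors, 62.3% (59.9 to 64.6) of passing genes with a mean over 100 were higher. That mean is over all 6 libraries, so a gene at 0 reads in control can reach it through its boron values alone. Aquaporin TIP1-3-like (LOC103929061), with 209 against 0 normalized counts, is such a gene. The floor is therefore not excluded, and the excess was absent at a mean over 1000 (42.8% higher, 37.4 to 48.3). Peel or other green tissue in the boron pulp cannot be told apart from an effect of boron: 16 of 18 peel markers were higher (Fisher's exact p = 0.184), 14 of the 18 had reads in every control library, non-specific lipid-transfer protein 2 rose to 643 ± 17.6 while the more abundant GDSL esterase/lipase 1-like gene fell to 305 ± 32.2, and pulp was sampled per the labels' protocols. A response to boron itself stays open as untested.

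Several genes of a glycolysis and fermentation list were lower in boron fruit. Pyruvate decarboxylase 2 (LOC103965128) fell from 33432 ± 1443 to 4697 ± 353, and pyruvate decarboxylase 1 (LOC103944123) from 17767 ± 261 to 4502 ± 73.3. An alcohol dehydrogenase-like gene (LOC103966279) fell from 2639 ± 112 to 285 ± 16.5. Cytosolic glyceraldehyde-3-phosphate dehydrogenase (LOC103949900) fell from 44220.0 ± 1356 to 15954 ± 1337, and enolase (LOC103963431) from 20706 ± 1695 to 8822 ± 165. A plant cysteine oxidase 2-like gene (LOC103942075), of a family of oxygen sensors, fell from 96.8 ± 24.1 to 1.26 ± 1.09. In the whole list 8 genes rose and 20 fell (4 and 20 with TMM), but its Fisher's exact p of 7.87e-07 is no evidence, since 11 of the members (1 higher, 10 lower) had been seen before the list was written. Among the 17 members not looked at before, 7 rose and 10 fell (Fisher's exact p = 0.00476), or 3 and 10 with TMM, so boron fruit may have had lower expression of these pathways. The larger share of falls among abundant genes stays open as a part of this: the p was 0.00799 among genes with a mean of at least 100 (2 rose, 8 fell) and 0.0549 with directions exchanged within 6 abundance classes. The list also holds genes that are not established as glycolytic: a probable cinnamyl alcohol dehydrogenase, which rose, and phosphoglycerate mutase-like genes, which moved both ways. The plant cysteine oxidase 2-like genes in it (LOC103942075 and LOC103956253, log2 fold changes -5.57 and -2.88) are not enzymes of these pathways either. Both were among the falls seen before the list was written.

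Boron fruit could have been less ripe, since the ACC oxidase 1 genes, a beta-galactosidase and a pectinesterase fell. Of the ripening list 27 genes rose and 8 fell, so 22.9% were lower (exact 95% interval 10.4 to 40.1), which was not told apart from the share among the other passing genes (Fisher's exact p = 0.705), and with TMM over the listed genes 18 were higher and 9 lower. Another ACC oxidase gene and expansin-A1 rose, an ACC synthase 1-like gene fell, and polygalacturonase genes moved both ways. The list holds genes of ACC synthase, ACC oxidase, polygalacturonase, pectate lyase, expansin and beta-galactosidase, and no pectinesterase. Expansins and pectate lyases make up most of it. The test of its direction as a whole gave no sign of delayed ripening and does not exclude it. The stage of the fruit at harvest is not given in the sources used here.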
